A study of Mus musculus with 3 samples.

How the data were processed

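The series holds bulk RNA-seq libraries from primary chondrocytes, the cells that make cartilage, taken from the knee joint cartilage of C57BL/6 mice. The 2 cKO libraries came from cells that carried Col2a1-CreERT2 and floxed alleles of Kdm6b, and the 1 control library came from cells with the floxed alleles alone. CreERT2 is a recombinase fused to part of an estrogen receptor, which 4-hydroxytamoxifen activates, and the Col2a1 promoter directs it to chondrocytes. Per the labels' protocols, cells of both genotypes were grown in F12 medium with 10% serum and received 1 µM 4-hydroxytamoxifen for 48 h. RNA was extracted with Trizol, RNA with an integrity number above 8 was depleted of ribosomal RNA, and libraries were made for the Ion Proton sequencer.

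The authors deposited 1 table of whole-number read counts per gene symbol, with 1 column per library, and the analysis started from these counts. The submitters' processing notes list the genome builds GRCm38 and GRCh37 without saying what each was used for. The aligner, the counting tool, the annotation and the use of strand are not given in the sources used here. Gene-level counts do not show which exon a read came from. Reads from near-identical copies, such as pseudogenes and the Oas, Gbp and H2 families, and from genes that overlap on either strand, could have been divided in ways that the table does not show. Values of such genes are uncertain. Positions are those of GENCODE M21 on GRCm38, and 30936 of the 44788 symbols in the table matched exactly 1 gene there.

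Column totals were 12577419 counts for cKO replicate 1, 12636471 for cKO replicate 2 and 12489738 for the control. Of the 44788 genes, 24051 had at least 1 count, and 15529 remained after edgeR's filterByExpr. The 2 cKO columns differed by far more than counting noise, with a chi-square of 9.82 per gene over 14813 genes, so they were treated as separate libraries. The labels do not say that they came from separate animals or cultures, but Xist had 2 counts in 1 of them and 10081 in the other, and Y-linked genes had counts only in the first, so they do not come from the same animal. The p-values measure only the spread between these 2 libraries, part of which may be technical.

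The comparison of cKO with control used edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the quasi-likelihood F test and Benjamini-Hochberg adjustment at a threshold of 0.05. The fit has 1 residual degree of freedom, from the pair of cKO libraries, so the lone control is assumed to vary like them. The test then leans on the prior variance shared across genes, whose estimated degrees of freedom were 19.9. Log2 fold changes are given with a standard error (SE) taken from the F test, as the size of the change divided by the square root of F. Where the control had few counts, this SE can be smaller than counting error alone. CPM values are counts scaled to TMM-normalised library size, and cKO means carry the SD of the 2 libraries. A rule without a test was run beside the model. It counted genes that differed from the control by at least 2-fold in each cKO library, with a prior count of 2, among the 11339 genes at a mean CPM of at least 5. Where the control had 1 to 3 counts, the fold is the ratio of normalised counts with an exact 95% binomial interval. Where it had 0, the fold is a lower bound against 3 counts in that library. These intervals and bounds cover counting error only.

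The 30 gene lists were fixed without sight of the counts. The 29 lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The test was repeated with an estimated correlation. The median of each list was also placed among 10000 random lists of the same size, matched on expression in 20 bins. The lists covered cartilage matrix, chondrocyte transcription and signalling, hypertrophy and mineralization, hedgehog, matrix proteases, inflammation and NF-kB, interferon-stimulated genes, H3K27 methylation machinery, Hox genes, cell cycle, p53, TGF-beta and BMP, Wnt, immediate-early genes, hypoxia and glycolysis, cholesterol and fatty acid synthesis, the unfolded protein and amino acid stress response, antioxidant (Nrf2) targets and sex-linked genes. They also covered markers of osteoblasts, fibroblasts and synovium, tendon, leukocytes, osteoclasts, endothelium, mural cells, skeletal muscle, adipocytes, nerve and glia, and red blood cells. Symbols were matched through older names where needed, as with Lect1 for Cnmd.

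The rule for named genes was fixed at the same time. It took Kdm6b and Kdm6a, then the 12 genes with the largest log2 fold change in each direction past the threshold, at a mean CPM of at least 5 and with both cKO libraries on one side of the control. Provisional symbols, small RNAs and mitochondrial genes were left out. It added the up to 4 members of each described list with the smallest p at that CPM, any list member past the threshold, and Col2a1, Acan and Sox9 as levels. Other genes are named only in the closing section and were chosen after their values were seen.

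The procedure was tested on simulated data with 200 changed genes among the 15198 genes it tested at the median. A first version, with a single data set and another model of the dispersions, gave 0 recovered genes with edgeR. The simulation was then changed to 20 data sets with added 8-fold changes and dispersions drawn around the trend, and 1 of the 20 could not be fitted. Over the other 19, edgeR recovered a median of 65.7% of 2-fold changes (range 0% to 83.6%), 97.0% of 4-fold changes (20.9% to 100%) and 100% of 8-fold changes (57.6% to 100%), with a median of 9 false calls (0 to 31). The prior degrees of freedom ranged from 3.10 to infinity, so the number of calls in a design of this size can swing widely. DESeq2 recovered 46.3%, 91.0% and 97.0% at those sizes, with a median of 3 false calls (0 to 5). The scatter of simulated dispersions around the trend was set close to the 19.9 prior degrees of freedom of the real fit, although that estimate belongs to the quasi-likelihood variance. Other settings on the real data gave lower estimates, such as 5.58 at a mean CPM of at least 5 and 2.03 without a filter on low counts. The simulation did not draw a scatter that wide. The simulated control was drawn with the same dispersions as the cKO libraries. All these rates therefore assume a control that varies like them, which 1 control library cannot check.

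Alternatives fixed before the data were examined were DESeq2-type size factors, upper-quartile factors, library totals only, no filter on low counts, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, the legacy edgeR quasi-likelihood test, and leaving out mitochondrial, ribosomal and small RNA genes. Each cKO library was also left out in turn, which gives values with no test. The size rule and the lists had their own alternatives. Alternatives chosen after seeing the data left out genes of chromosomes X and Y, left out the interferon list, used a robust prior, or set the prior degrees of freedom to 3, 5 or 10. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Some genes that passed the test are not reported here by name, although list counts and medians include them.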

Results

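RNA was measured in primary knee-joint chondrocytes with floxed Kdm6b. The cells either carried the chondrocyte-directed, tamoxifen-activated recombinase (cKO, 2 libraries) or lacked it (control, 1 library), and both genotypes received 4-hydroxytamoxifen. The libraries were of like depth, between 12489738 and 12636471 counts. The comparison asked which transcripts differ in chondrocytes that carry the recombinase directed at floxed Kdm6b. This gene encodes a demethylase that removes repressive methyl groups from histone H3. Col2a1, the main collagen of cartilage, was abundant in each library, at 12527 and 11984 CPM in cKO and 20116 CPM in the control. Over 11339 genes at a mean CPM of at least 5, the SD of the log2 difference was 0.331 between the cKO libraries, against 0.569 and 0.562 between each of them and the control.

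Kdm6b itself (chromosome 11, 69398508 to 69413675, minus strand, GRCm38) had 1049 and 948 counts in the cKO libraries and 1289 in the control, or 84.2, 74.1 and 103.9 CPM. Its log2 fold change was -0.39 ± 0.14 (SE), with an adjusted p of 0.138 in edgeR, so the difference did not pass the test. The gene-level counts also include exons outside the floxed part, and an antisense gene, Kdm6bos, overlaps its exons, so this value checks the genotype labels only weakly. Kdm6a, the related demethylase on chromosome X, differed by 0.04 ± 0.20 (adjusted p = 0.957 in edgeR). It lay at 25.1 CPM in cKO replicate 1 and 38.2 CPM in cKO replicate 2, on either side of the control at 30.7 CPM. The cKO libraries differ in sex-linked transcripts, so their mean does not show an unchanged level of this X-linked gene.

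**Figure D1:**
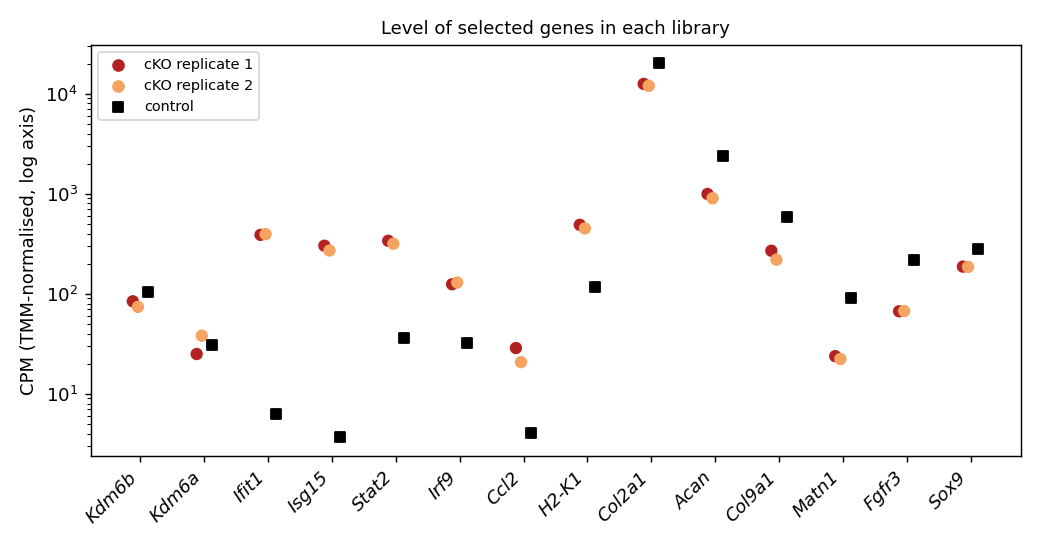
TMM-normalised CPM (log axis) of 14 genes in each library, with circles for the 2 cKO libraries and squares for the 1 control library. Ifit1 lies near 392 CPM in cKO against 6.37 in the control, whereas Acan lies near 948 CPM against 2400.

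The list with the largest rise in cKO chondrocytes was that of interferon-stimulated genes, the antiviral genes that cells switch on downstream of interferon receptors. Of the 34 measured members of this list, 34 rose and 0 fell, both over all genes and adjusted over the list alone, and each of the 34 was higher in both cKO libraries. Isg15, a ubiquitin-like modifier, rose 77.2-fold (log2 6.27 ± 0.21 SE), from 3.71 CPM to 287 ± 22 CPM (SD, n = 2). Ifit1, which binds foreign RNA, rose 61.4-fold, and Usp18, which removes Isg15 from proteins, rose 76.8-fold. The list median was 4.89 on the log2 scale, and it lay at 4.89 in cKO replicate 1 and 4.78 in cKO replicate 2.

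The rise ran through the layers of the interferon response. The signalling factors Stat2 and Irf9, which act downstream of type I interferon, rose 9.02-fold and 3.91-fold, and Irf7, which drives interferon genes, rose 38.8-fold. The RNA sensors Ddx58 and Ifih1 rose 5.52-fold and 13.4-fold. Among effectors, Rsad2, which encodes viperin, rose 128-fold, and the nucleic acid sensor Zbp1 rose 88.7-fold. These 2 folds are imprecise, since the control had only 5 and 4 counts. The smallest rise in the list was that of Ifit2, at 2.20-fold, from 22.8 CPM in the control.

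The oligoadenylate synthetase family took 6 of the 12 places for the largest rises, in 2 clusters on chromosome 5 (GRCm38). Its enzymatically active members, which are not all of them, make the activator of the RNA-cutting enzyme RNase L. Oas2, Oas3, Oas1g and Oas1a lie between 120730333 and 120907521, and Oasl2 and Oasl1 between 114896936 and 114937915. Oasl2 rose by 8.17 ± 0.25 and Oas2 by 6.76 ± 0.30 on the log2 scale (SE), from only 8 and 7 control counts. Oasl1 had 179 and 238 counts in cKO and 0 in the control, which makes it at least 68.3-fold higher. Oas1a had 2 control counts, a fold of 415 (95% interval 115 to 3431), Oas3 had 2, a fold of 221 (60.9 to 1824), and Oas1g had 1, a fold of 235 (41.9 to 9294). Reads may be shared among these near copies, so the split between single genes is uncertain.

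The other places for the largest rises went to Iigp1, an immunity-related GTPase, at 6.71 ± 0.28 on the log2 scale (SE), to Sp100, Ifi203, Rsad2 and Zbp1, and to Xist. Sp100, a nuclear body protein, had 1 control count and a fold of 223 (95% interval 39.8 to 8829). Ifi203 had 3 control counts and a fold of 95.8 (32.6 to 466), and it shares exon sequence with the neighbouring gene Mndal. Xist, the RNA that silences an X chromosome in female cells, had 10081 counts in cKO replicate 2 but 2 in cKO replicate 1 and 1 in the control. Its call therefore rests on cKO replicate 2, and without that library 2 counts stand against 1.

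The interferon list differed from other genes in camera with an adjusted p of 1.66e-57 at the preset correlation. That p compares genes with genes within these libraries and is not evidence from replicate cultures. With an estimated correlation the p was 0.0465 before adjustment and the adjusted p was 0.863. All 34 members rose in DESeq2 and in limma-voom as well, and 31 rose with the prior degrees of freedom set to 3. Markers of macrophages and leukocytes, with 6 of 24 measured, had a median log2 fold change of 0.77 (camera adjusted p = 0.00170; adjusted p = 0.863 with an estimated correlation). Of these 6, 0 passed the edgeR test over all genes, in DESeq2 or in limma-voom, 2 had an unadjusted p under 0.05, and 1 passed adjusted over the list alone.

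**Figure D2:**
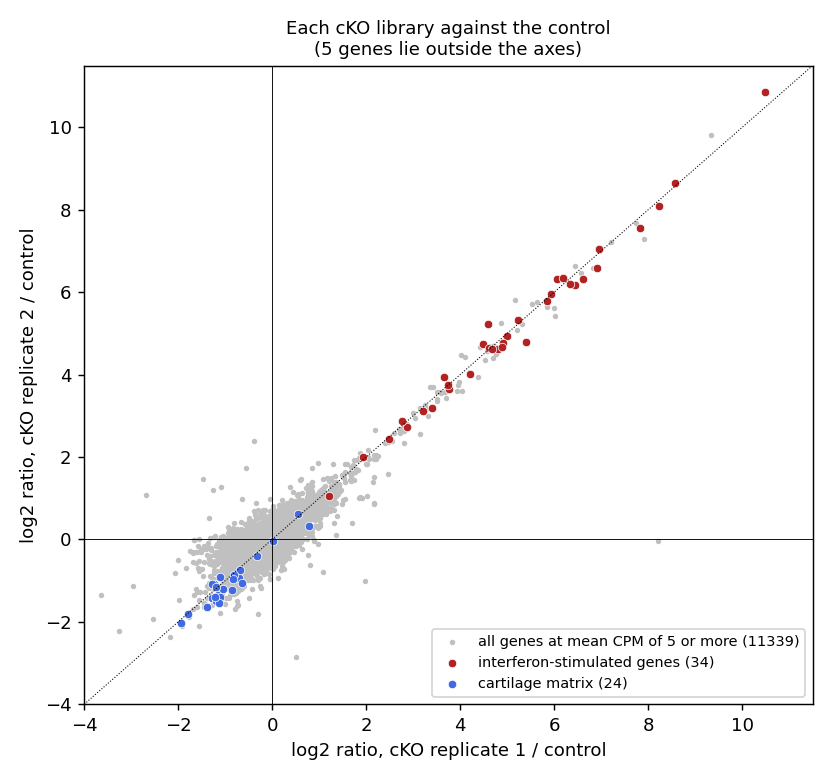
Log2 ratio of each cKO library to the control, with cKO replicate 1 on the x axis and cKO replicate 2 on the y axis, for 11339 genes at a mean CPM of at least 5 (grey points). The 34 interferon-stimulated genes (red) lie along the diagonal above 0, most cartilage matrix genes (blue) lie below 0 in both libraries, and 5 genes, Xist and 4 Y-linked genes, lie outside the axes.

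Cartilage matrix genes were lower in the cKO chondrocytes. Of 29 measured members, 22 fell, 2 rose and 5 did not pass the edgeR test, and adjusted over the list alone 24 fell and 2 rose. Acan, which encodes the main proteoglycan of cartilage, fell to 948 ± 66 CPM (SD, n = 2) from 2400 CPM, a log2 change of -1.34 ± 0.17 (SE, adjusted p = 8.31e-06 in edgeR). Matn1 (chromosome 4, 130944385 to 130955475, GRCm38), a matrix filament protein, fell by 1.99 ± 0.15 on the log2 scale (SE), and Ucma, a secreted cartilage protein, fell by 1.79 ± 0.16. The list median was -1.15, at -1.11 in cKO replicate 1 and -1.16 in cKO replicate 2.

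Collagens other than Col2a1 were among the genes that fell. Genes for type IX collagen fell together, with log2 changes of -1.25 for Col9a1, -1.01 for Col9a2 and -0.84 for Col9a3, and Col11a1, Col11a2 and Col27a1 fell by 0.82, 1.26 and 1.33. Hapln1, which links aggrecan to hyaluronan, fell by 1.18, and Comp, which binds collagen fibrils, fell by 0.83. Of the leucine-rich repeat proteoglycans in the list, Dcn, Lum and Epyc fell by 1.12, 0.89 and 1.17, and Prelp rose. For 2 others, among them the most abundant at 4246 CPM, the difference did not pass over all genes. Of these 2, Fmod, at -0.37, passed adjusted over the list alone (adjusted p = 0.0412 in edgeR). Lect1, which encodes the anti-angiogenic protein chondromodulin, fell by 1.51, and Susd5 by 1.31. The members that rose were Prelp, at 0.58 ± 0.16 (SE), and Prg4, which encodes the joint lubricant lubricin, at 0.56 ± 0.16, and in DESeq2 Prelp passed but Prg4 did not (adjusted p = 0.308). Col2a1 had a log2 fold change of -0.71 ± 0.33 with an adjusted p of 0.283 in edgeR, so the most abundant gene of the list did not pass there, although it passed adjusted over the list alone (adjusted p = 0.0447), in DESeq2 (adjusted p = 0.000663) and in limma-voom.

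Camera gave the cartilage matrix list an adjusted p of 3.25e-15, and with an estimated correlation the adjusted p was 0.863. The number of members that fell was 17 in DESeq2, and it was 12 with the prior degrees of freedom set to 5 and 2 with them set to 3, and under either of these settings none rose. Markers of mural and smooth muscle cells moved the other way, with a median of 0.52 over 11 members (camera adjusted p = 0.0164; adjusted p = 0.863 with an estimated correlation). Of these 11, 0 passed over all genes in edgeR, DESeq2 or limma-voom, 2 had an unadjusted p under 0.05 and 1 passed adjusted over the list alone, and among members at a mean CPM of at least 5 the list's adjusted p was 0.0681. The leading member, Actg2, had 10.1 ± 4.1 CPM (SD, n = 2) in cKO and 4.76 CPM in the control, with an adjusted p of 0.0740 in edgeR.

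Some regulators of chondrocyte identity were also lower, while most did not pass. Of 21 measured genes for chondrocyte transcription and signalling, 7 fell, 2 rose and 12 did not pass, and adjusted over the list alone 10 fell and 2 rose. Fgfr3 (chromosome 5, 33721674 to 33737068, GRCm38), the receptor that restrains chondrocyte proliferation, fell to 67.2 ± 0.3 CPM (SD, n = 2) from 215 CPM, a log2 change of -1.68 ± 0.13 (SE). Sox9, the master transcription factor of chondrocytes, fell by 0.58 ± 0.13 (adjusted p = 0.00876 in edgeR) and its partner Sox6 by 0.65 ± 0.13, but in DESeq2 neither passed (adjusted p = 0.0655 and 0.0579). Wwp2, whose introns hold a cartilage microRNA, fell by 0.85, and Scrg1, Gdf10 and the parathyroid hormone receptor gene Pth1r fell by 1.35, 0.76 and 0.81. Gdf5, a joint-forming growth factor, rose by 0.66 ± 0.18, and Pax9 rose by 1.81 ± 0.42 from 1.93 CPM. DESeq2 called 3 members lower and none higher, and with the prior degrees of freedom set to 3 edgeR called 1 lower. The list median was -0.38 (camera adjusted p = 0.00156; adjusted p = 0.863 with an estimated correlation).

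Genes of hypertrophy and mineralization, the late program of growth plate chondrocytes, went both ways. Of 19 measured, 2 rose and 3 fell, against 1 and 2 in DESeq2, and adjusted over the list alone 4 rose and 4 fell. Smpd3, a sphingomyelinase needed for mineralization, had the largest fall among named genes at a mean CPM of at least 5, by 2.27 ± 0.23 (SE, adjusted p = 3.35e-07 in edgeR), and the channel gene Panx3 and the bone matrix gene Ibsp fell by 1.41 and 0.82. Ank and Enpp1, which supply the mineralization inhibitor pyrophosphate, rose by 0.67 and 0.53. The list did not shift as a whole, and its median of 0.08, mean of -0.08 and downward camera direction (adjusted p = 0.976) differed in sign. The hedgehog list had a median of -0.13 (camera adjusted p = 0.322), and 1 of its 11 members, the co-receptor gene Boc, fell, by 0.55 ± 0.14, but did not pass in DESeq2.

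The remaining places for the largest falls went to genes outside the lists above. G0s2, an inhibitor of triglyceride lipase, fell by 2.20 ± 0.26 on the log2 scale (SE), and the scaffold protein gene Dlg2 fell by 1.98 ± 0.31. Scin, which encodes an actin-severing protein, fell to 3.25 ± 0.29 CPM (SD, n = 2) from 13.1 CPM. Car3, a carbonic anhydrase, fell by 1.83 ± 0.31, and Frzb, a secreted Wnt antagonist of joint cartilage, fell by 1.80 ± 0.20. The other places were taken by Rps13-ps4, Rpl10-ps3 and Usf2-ps1, whose symbols mark pseudogenes, and these values are uncertain because near copies can share reads. In DESeq2 Car3 (adjusted p = 0.0796), Rps13-ps4 and Usf2-ps1 (both near 1) did not pass, while the other falls named here did. Rps13-ps4 had 51 and 260 counts in cKO and 638 in the control. Ribosomal protein genes and pseudogenes together took 1.20% and 1.53% of counts in cKO and 1.69% in the control, and ribosomal RNA took 0.331%, 0.532% and 0.647%.

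Inflammatory genes rose in part. Of 28 measured inflammation and NF-kB targets, 10 rose and 0 fell, and adjusted over the list alone 13 rose. The number that rose was 5 in DESeq2, and it was 2 with the prior degrees of freedom set to 5 and 0 with them set to 3. The monocyte-attracting chemokine genes Ccl2 and Ccl7 rose by 2.59 ± 0.27 and 1.88 ± 0.25 on the log2 scale (SE), which is 6.01-fold and 3.68-fold. Ccl5, another chemokine gene, had 77 and 123 counts in cKO and 2 in the control, a fold of 49.1 (95% interval 13.4 to 408). Irf1 rose 2.04-fold, and Ptgs2 and Ptges, which act in prostaglandin synthesis, rose 1.71-fold and 1.85-fold, but in DESeq2 Irf1 and Ptges did not pass (adjusted p = 0.0822 and 0.177). The list median was 0.52 (camera adjusted p = 2.40e-05; adjusted p = 0.863 with an estimated correlation), beside the median of 0.77 for leukocyte markers.

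Several lists of growth and stress genes differed by small amounts from other genes in camera at the preset correlation, against 1 control library. For each list in this paragraph that camera called, the adjusted p was 0.863 with an estimated correlation. Of 28 immediate-early genes, 7 rose over all genes, among them Fosl1 by 1.01 ± 0.19 on the log2 scale (SE), Dusp6 by 0.95 ± 0.20 and Klf4 by 0.79 ± 0.14, while adjusted over the list alone 10 rose and 2 fell (median 0.35, camera adjusted p = 0.00503). Of 28 p53 targets, 5 rose, led by Perp at 1.29 ± 0.22 and Phlda3 at 0.83 ± 0.14, and adjusted over the list alone 9 rose and 1 fell (median 0.24, camera adjusted p = 0.00561). Of 40 cell cycle genes, 3 rose, both over all genes and adjusted over the list alone. These were Ccnd1, the gene of cyclin D1, at 733 CPM against 366, Rrm2 and Mcm5 (median 0.19, camera adjusted p = 0.00231). In hypoxia and glycolysis, 2 of 33 rose under either adjustment, Hk1 by 0.50 ± 0.14 and Gapdh by 0.97 ± 0.25, the latter at only 14.2 CPM in cKO with many pseudogene copies (median 0.13, camera adjusted p = 0.0218). In the unfolded protein and amino acid stress response, Trib3 fell by 1.02 ± 0.13, Chac1 by 0.57 and Herpud1 by 0.46, so 3 of 31 fell and 8 fell adjusted over the list alone (median -0.17, camera adjusted p = 0.0136). DESeq2 called 2 immediate-early genes, 2 p53 targets and 1 cell cycle gene higher, 1 gene of the stress response lower and no hypoxia gene.

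The chromatin and patterning lists did not shift. Of the 33 measured genes of the H3K27 methylation machinery, 0 passed the edgeR test over all genes or adjusted over the list alone. Of the 33, 2 had an unadjusted p under 0.05 and 0 passed in DESeq2, while 1 fell in limma-voom (median 0.03, camera adjusted p = 0.733). The lowest member, Uty at -0.89, is Y-linked and had 219 counts in cKO replicate 1, 0 in cKO replicate 2 and 201 in the control. Its value therefore reflects the missing Y-linked counts of cKO replicate 2. Of 27 Hox genes, 0 passed under either adjustment, in DESeq2 or in limma-voom, and 1 had an unadjusted p under 0.05 (median -0.03, camera adjusted p = 0.733), and the leading member Hoxa10 had a log2 fold change of -0.43 ± 0.13 (SE, adjusted p = 0.0768 in edgeR). Over all 15529 genes tested, 2431 had an unadjusted p under 0.05.

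Signalling and metabolic lists held single genes that changed without a shift of the whole list in camera. Among the matched random lists, the Wnt median lay at percentile 98.2, and the other medians of this paragraph lay between 70.8 and 83.9. In the TGF-beta and BMP list (median 0.08, camera adjusted p = 0.318) 3 of 32 rose, among them Ltbp2 and Inhba by 0.93 and 0.68 on the log2 scale, and 1 fell, the BMP antagonist gene Nog, by 1.08, while adjusted over the list alone 6 rose and 2 fell. In the Wnt list (median 0.17, camera adjusted p = 0.325) Frzb and Nkd1, both inhibitors of the pathway, fell, and Sfrp1, another inhibitor, rose by 1.66 ± 0.34 (SE), with the same counts adjusted over the list alone. Sfrp1 lay at 40.5 and 16.8 CPM in cKO and 9.03 CPM in the control. Among matrix proteases and inhibitors (median 0.06, camera adjusted p = 0.325) 2 rose, among them Timp1 by 0.78, and 2 fell, Adamts9 and Htra1, by 0.91 and 0.54, with the same counts adjusted over the list alone. The lipid regulator Srebf1 fell by 0.64 in the cholesterol and fatty acid list, the 1 member to pass under either adjustment (median 0.06, camera adjusted p = 0.686). In the antioxidant list (median 0.08, camera adjusted p = 0.321) Hmox1 and Gclc rose by 0.65 and 0.62, and adjusted over the list alone 2 rose and 1 fell. DESeq2 called 2 genes higher in the TGF-beta and BMP list, 2 higher among proteases and inhibitors, 1 higher in the antioxidant list, 1 lower in each of the Wnt and cholesterol lists, and no others.

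Markers of other connective tissue cells moved in different directions. Of 25 fibroblast and synovium markers, Tnxb, Ly6a, Thy1 and Prg4 rose and Dcn, Lum and Col14a1 fell, and adjusted over the list alone 5 rose and 4 fell (median 0.05, camera adjusted p = 0.880). Thy1 was uneven, with 623 and 259 counts in cKO and 139 in the control. Of 12 osteoblast markers, Omd and Ibsp fell, by 1.05 and 0.82, and 3 fell adjusted over the list alone (median -0.16, camera adjusted p = 0.325). Angptl7 rose by 1.26 ± 0.15 (SE) among 9 tendon and ligament markers (median 0.17, camera adjusted p = 0.686), and adjusted over the list alone 1 rose and 1 fell. DESeq2 called 1 fibroblast marker higher and 2 lower, 1 tendon marker higher and no osteoblast marker. Of 5 osteoclast, 5 skeletal muscle, 5 adipocyte and 7 nerve and glia markers, 0 passed in edgeR under either adjustment, in DESeq2 or in limma-voom, and 0, 0, 1 and 2 had an unadjusted p under 0.05, with list medians of 0.17, 0.02, 0.13 and 0.00 and camera adjusted p of 0.322, 0.577, 0.527 and 0.688. Of 5 endothelial markers, 0 passed over all genes in edgeR, DESeq2 or limma-voom and 2 had an unadjusted p under 0.05, while 1 rose and 1 fell adjusted over the list alone (median 0.56, camera adjusted p = 0.431). The red blood cell list had 1 measured member and was not tested. Of 9 sex-linked genes, Xist alone passed in edgeR, under either adjustment, whereas in DESeq2 none passed (Xist at an adjusted p of 0.211) and in limma-voom 4 fell and 0 rose (median 0.04, mean 1.00, camera downward with an adjusted p of 0.880).

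**Figure D3:**
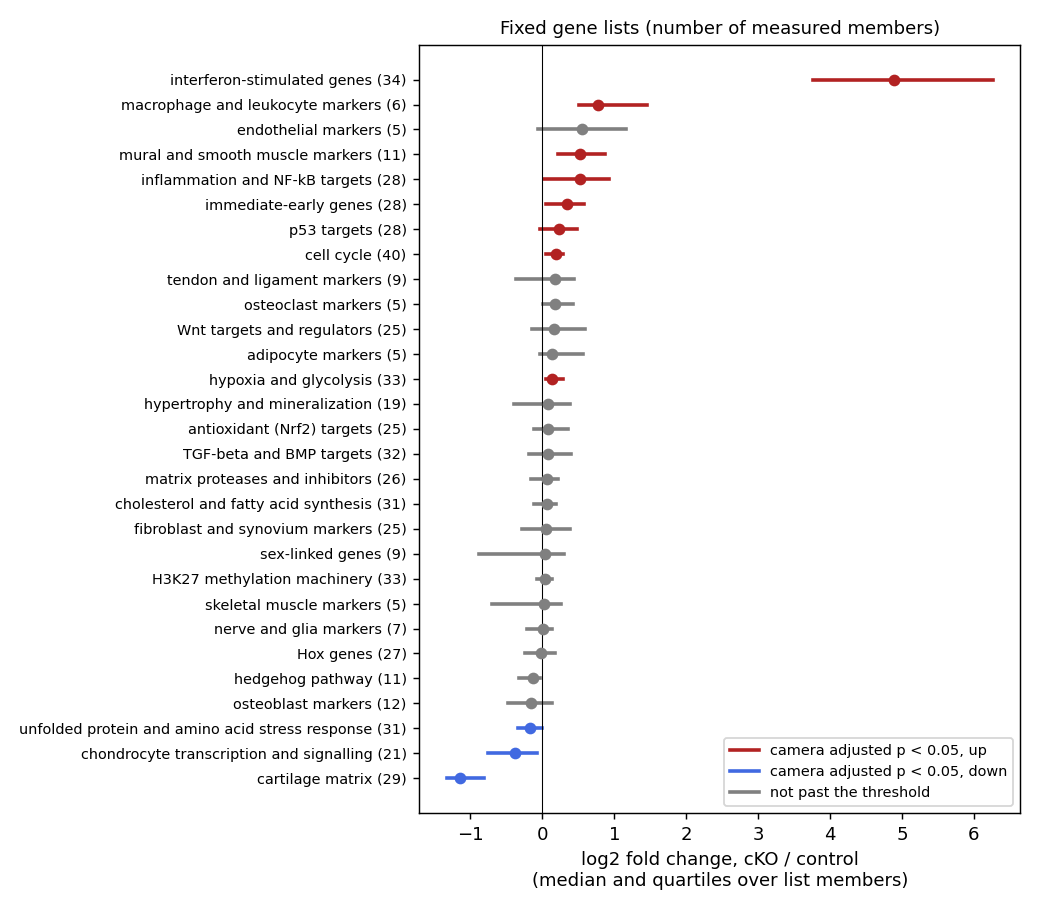
Median (point) and quartiles (bar) of the log2 fold change between cKO and control over the measured members of 29 gene lists, with the number of members in brackets. The interferon list lies at 4.89, the cartilage matrix list at -1.15, and the other lists between -0.38 and 0.77.

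In total, 467 genes rose and 295 fell in cKO at an adjusted p under 0.05 in edgeR, of 15529 tested, and the median log2 fold change was 1.14 among the first and -0.86 among the second. By size alone, 182 genes were at least 2-fold higher and 56 at least 2-fold lower in both cKO libraries. The 61.3% share of rises among the calls was 71.8% with library totals only, which called 227 rises and 89 falls, and 55.3% with upper-quartile factors, and DESeq2 called 227 and 83. Calls fell to 83 rises and 4 falls with the prior degrees of freedom set to 3, and to 0, with 1829 genes at an unadjusted p under 0.05, without a filter on low counts, so the counts depend on a spread that 1 residual degree of freedom hardly fixes.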

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

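The prior degrees of freedom of 3, 5 and 10, the robust prior and the fits without X and Y genes or without the interferon list were chosen after seeing the data. The 467 rises and 295 falls became 227 and 89 with library totals only, 201 and 89 at a mean CPM of at least 5, and 227 and 83 in DESeq2, of which 227 and 82 were shared with edgeR. Without a filter on low counts edgeR called 0 and 0, with 1829 genes at an unadjusted p under 0.05. With the prior degrees of freedom set to 3, 5 and 10 it called 83 and 4, 151 and 42, and 309 and 152. The estimated prior degrees of freedom were 19.9 in the reported analysis, 6.00 with totals only, 5.58 at a mean CPM of at least 5 and 2.03 without the filter, and setting a lower value alone gave fewer calls. The cause of the lower DESeq2 count was not tested. The other alternatives stayed within 1.5 times, between 399 and 531 rises and between 230 and 361 falls. The share of rises was 55.3% with upper-quartile factors, 56.3% in limma-voom, 71.8% with totals only, 73.2% in DESeq2, 78.2% at 5 and 95.4% at 3, against 61.3%.

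Of the 130 named genes past the threshold, 84 kept their call in DESeq2, 128 in limma-voom, 117 with DESeq2-type size factors and 37 with the prior set to 3, and none changed direction under any alternative. Kdm6b stayed below the control and short of the threshold throughout, with adjusted p from 0.0955 to 0.95. Ctsk, which did not pass at 0.01, was at -0.024 with upper-quartile factors, which moved the median of all genes alike, from -0.0022 to -0.0337, and the hypertrophy list median, 0.08, was -0.0057 over members at a mean CPM of at least 5, once 2 members with positive values and 1 with a negative value had dropped out. The 11 lists called by camera became 0 with an estimated correlation. The size of the correlation alone does not account for this. For p53 targets it was estimated at 0.0106, close to the preset 0.01, yet camera's unadjusted p went from 0.00155 to 0.196. With an estimated correlation, camera takes its degrees of freedom from the libraries, which leave 1, rather than from the number of genes. At the preset correlation the 11 lists became 10 over members at a mean CPM of at least 5. The mural list dropped out there (camera adjusted p = 0.0681) and the osteoblast list entered, lower (camera adjusted p = 0.0322). The leukocyte list had fewer than 5 members.

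By size alone, 182 genes were 2-fold higher in both cKO libraries, 301 at a mean CPM of at least 1 and 109 at 20, and 220 to 236 with 1 cKO library left out. The 56 genes that were 2-fold lower became 103 and 23 at those limits, as more or fewer genes enter the rule, and 103 to 168 with 1 cKO library left out, where 1 library alone has to pass. Leaving out a cKO library leaves 1 against 1, so no calls could be counted. No paired analysis was possible because there is 1 control library.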

Other observations

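The genes named in this part, the gene groups in this part and the tests of sex, of single cultures and of transgene reads were chosen after the results were seen. Genes for antigen presentation on MHC class I rose with the interferon-stimulated genes. Of 24 tested members of the pathway, 19 rose and 0 fell in edgeR, with a median log2 fold change of 1.89. B2m, the light chain, rose from 147 CPM to 531 and 580 CPM, H2-K1 rose 4.04-fold and H2-D1 rose 4.28-fold, although the H2 genes are near copies that can share reads. The peptide transporter gene Tap1 rose 6.43-fold, the immunoproteasome gene Psmb8 rose 23.5-fold, and Nlrc5, which activates class I genes, rose 35.6-fold. The chaperone genes Calr, Canx and Pdia3 were among the 5 members that did not pass. Of 7 genes of the MHC class II pathway, only 3 had enough counts to be tested. Of these 3, 0 passed in edgeR and 0 had an unadjusted p under 0.05, and H2-Ab1 had a log2 fold change of 0.08 ± 0.17 (SE, adjusted p = 0.878 in edgeR). Among the untested genes, H2-Aa had 0 counts in each library, and Cd74 had 3, 1 and 3 counts in cKO replicate 1, cKO replicate 2 and the control. The class II pathway was therefore largely below detection.

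The interferon genes themselves were barely detected. Ifnb1 had 1, 1 and 0 counts in cKO replicate 1, cKO replicate 2 and the control, and Ifna4 had 2, 0 and 0, so no difference was detectable at this depth. The gene of the double-stranded RNA receptor Tlr3 rose by 2.02 on the log2 scale, and Tmem173, which encodes the DNA-sensing adaptor STING, rose by 0.80 (adjusted p = 0.00793 in edgeR). Mb21d1, which encodes the DNA sensor cGAS, Mavs and Irf3 did not pass, with log2 fold changes of 0.70, 0.03 and -0.02. On the cartilage side, 6 of 25 tested genes of chondroitin sulfate synthesis fell and 0 rose, with a median of -0.22. They were Slc26a2, the sulfate transporter gene, at -0.98 ± 0.14 (SE), Papss2 at -0.94, Chsy3 at -0.86, Chst11 at -0.74, Csgalnact1 at -0.71 and Papss1 at -0.49.

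The libraries differed in sex-linked transcripts. Xist had 10081 counts in cKO replicate 2, against 2 in cKO replicate 1 and 1 in the control. The Y-linked genes Ddx3y and Kdm5d had 0 counts in cKO replicate 2, 680 and 505 in cKO replicate 1, and 732 and 460 in the control.

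The rise of interferon-stimulated genes in both cKO libraries was weighed against 3 other explanations. A difference in sex is argued against, since in cKO replicate 1, whose sex-linked counts match the control, the list median was 4.89, although this is 1 library. Leukocytes in the cKO cultures are also argued against as the source of these reads, though not as cells that act on the chondrocytes. Together 10 leukocyte transcripts, among them Lyz2, Tyrobp, Csf1r and Ptprc, gained at most 0.670% of the CPM that Ifit1 alone gained, or 2.56 CPM against 382 CPM. A difference between single cultures or batches cannot be told apart from the genotype with 1 control library. Such a difference could be an infection or an innate response in the cKO cultures. The control also lacked Col2a1-CreERT2, so carrying the recombinase cannot be told apart from a loss of Kdm6b. An effect of Kdm6b loss therefore remains an untested hypothesis.

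The fall of cartilage matrix genes is open in the same way. Sex is argued against by the list median of -1.11 in cKO replicate 1. A smaller share of chondrocytes could lower the list, and should then raise the markers of the other cell types. The mural median of 0.52 goes with this, but the fibroblast median was 0.045 and the lowest of the 3 was -0.158, for osteoblasts, whose list was lower over members at a mean CPM of at least 5 (median -0.165, camera adjusted p = 0.0322), and these go against it. Fibroblast markers went both ways, and 7 of the 25 measured also stand in other lists, among them Dcn, Lum and Prg4 in the cartilage matrix list. The osteoblast quartiles over all members ran from -0.48 to 0.13, and 7 of the 12 measured osteoblast markers also stand in other lists, such as hypertrophy. These values therefore do not decide, and a loss of chondrocytes cannot be told apart from lower expression per cell.

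Esr1, the estrogen receptor gene (chromosome 10, 4611593 to 5005614, GRCm38), had 445 and 428 counts in cKO and 39 in the control, a log2 fold change of 3.46 ± 0.24 (SE, adjusted p = 5.95e-10 in edgeR). A candidate explanation is reads from CreERT2, which carries part of the human receptor and is present only in the cKO genotype. The log2 fold change was 3.41 in the lower of the cKO libraries, but this rise prompted the explanation and so does not test it. Gene-level counts cannot separate transgene reads from the mouse gene, so the sources cannot be told apart. The receptor target genes Pgr and Greb1 had 3, 2 and 2 and 11, 2 and 1 counts in cKO replicate 1, cKO replicate 2 and the control, too few to decide.

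Taking each library in turn as the lone one gives 3 splits. The real split called 762 genes and each of the others called 1, so 1 of 3 splits called as many, and with 3 splits the share cannot fall under 0.05. In the other splits a cKO library and the control form the pair that sets the spread, so their difference itself limits the calls. A control culture that differed for any reason would give the same contrast, so the splits do not bear on the genotype.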
